A study of Homo sapiens with 18 samples.

How the data were processed

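RNA was measured in MCF7, an established human breast adenocarcinoma cell line, with CEL-seq2, which tags each sample with a barcode and sequences fragments from the 3′ ends of polyadenylated transcripts. Cells were grown in DMEM and incubated with 54 µM phenolaTi, a titanium-based anticancer compound, for 3, 6, 15, 24 or 48 h, or left untreated. Per the labels' protocols, all incubations ended at the same harvest. No vehicle-treated cells were named. Each of the 6 groups held 3 libraries, and the labels number them as repeats 1 to 3.

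The authors deposited a table of raw read counts per gene for 18 libraries and 50026 Ensembl gene IDs. The submitters' processing notes name cutadapt, STAR, HTSeq and the GRCh38 genome build, without versions, roles or order. The annotation release, the use of strand in counting and the collapsing of molecular identifiers are not given in the sources used here. A deposited metadata sheet, per its column headers, gives the count of input reads, the count of uniquely mapped reads and their percent for 16 libraries, and 1 of 3 batch letters for each. It does not list replicate 1 of 15 h or replicate 3 of 24 h. In all 16 listed libraries batches A, B and C held replicates 1, 2 and 3. Input reads ranged from 3969181 to 13454034 per library, and 62.14% to 66.59% of them were uniquely mapped. In 13 of the 16 libraries the gene counts summed to more than the uniquely mapped reads, at 0.801 to 1.28 counts per uniquely mapped read. Reads mapped to several places, reads counted for more than 1 gene or a sheet made from other reads could each give this, which was not tested, and genes with near-identical copies are given as uncertain. Size-normalised counts, FPKM tables, sample distances, cluster data, centred and scaled tables and a supplementary table of 16 libraries without names were not used here. All 18 count columns were used and the number of unused sample columns was 0.

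Symbols were found for 34283 of the 50026 gene IDs (68.53%) and coordinates for 49304 in GENCODE 29 on GRCh38. At least 1 count was found for 38408 genes. Total counts ranged from 2124367 to 9872424 per library, of 96665956 counts in all. Intervals and floors cover counting error only and treat the counts as independent molecules, which they may not be. The spread between libraries is left out, so the intervals may be too narrow. A floor is 3 counts summed over the 3 libraries of a group. For genes with 1 to 3 counts in a group the ratio of summed, scaled counts is given with its 95% interval from the exact binomial distribution.

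Genes were filtered with filterByExpr by group, which left 13211 tested genes, and libraries were scaled with TMM. Counts were fitted with 6 group means over all 18 libraries in 1 edgeR quasi-likelihood model (glmQLFit and glmQLFTest), with 12 residual degrees of freedom and a common biological coefficient of variation of 23.8%. Each time was tested against untreated cells, consecutive times were tested against each other, and all 5 times were tested together. Benjamini-Hochberg adjusted p-values under 0.05 were called. Every adjusted p for a gene is from this edgeR test unless another is named. Log2 changes are given ± SE from this model, and CPM is TMM-scaled counts per 1e6 counts as mean ± SD over 3 libraries. Medians of each list in each treated library against the untreated mean were computed after the results were seen. "Rose" and "fell" are relative to TMM scaling. The 3 treated libraries of a comparison share their 3 untreated libraries with every other time. Calls of a gene or list at several times are therefore not independent findings, and no count of calls shared between times is reported.

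The 25 gene lists were fixed before the data were examined. They cover the PERK-ATF4 integrated stress response, ER chaperones and ER-associated degradation, the HSF1 heat shock response, the NRF2 oxidative stress response, metallothioneins and zinc transport, iron handling, p53 targets, sterol synthesis and uptake, DNA replication and S phase, mitosis and G2/M, the estrogen response, luminal epithelial identity, cytosolic ribosomal proteins, ribosome biogenesis, the nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, hypoxia and glycolysis, NF-kB and inflammatory cytokines, the interferon response, immediate early genes, autophagy and lysosome, BCL2 family and death receptors, fibroblast and mesenchymal markers, leukocyte markers and nuclear-retained RNAs. Lists were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes, and p-values were adjusted over the 125 tests of 25 lists at 5 times. Camera was repeated with an estimated correlation and the same adjustment. Members that rose or fell were counted over all genes and adjusted over the list alone.

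Genes were named by a rule set at the same time. For each time against untreated cells, it took genes with adjusted p under 0.05, a mean of at least 20 raw counts per library over the 6 libraries compared, and all 3 treated libraries on the same side of all 3 untreated libraries in CPM. The 8 largest log2 changes in each direction were named, or 4 for consecutive times, and up to 4 members with the smallest adjusted p for each list. Genes without a symbol and Y-linked genes were passed over. A fixed set of 22 genes was always reported: HSPA5, HSP90B1, DNAJB9, HERPUD1, SDF2L1, XBP1, ATF4, DDIT3, TRIB3, CHAC1, ASNS, ATF3, GDF15, HMOX1, HSPA1A, MT2A, CDKN1A, MKI67, MCM2, CCNB1, TFF1 and GREB1.

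Replicates of a group correlated at 0.948 to 0.984 (Pearson, log2 CPM, 9047 genes with a mean of at least 20 counts, 18 pairs), and a chi-square test of their counts gave 3.96 to 47.1 per degree of freedom, so no pair held the same counts under both names. The batch letters make the replicate number a shared batch, and a model with replicate number as a block was fitted as an alternative. Of the 45 pairs of libraries with the same number in different groups, 19 had deviations from their group means that correlated over 0.1, with a range of -0.286 to 0.455. The deviation of 12 of the 18 libraries matched its own number best.

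The procedure was tested on counts simulated from the real means and library sizes of the 13211 genes, with 100 genes changed 2-fold and 100 changed 4-fold. For 3 h against untreated, edgeR recovered 35% and 94% of them with 13 false calls (9.15% of its calls), and for 48 h 34% and 87% with 2 false calls (1.63%). Camera called the simulated risen list and 0 of 24 unchanged lists in both. Genes were simulated independently of each other, from the means of untreated cells, and the unchanged lists were random genes. False calls of lists whose genes vary together could therefore not show. The changed genes were few and rose and fell in equal number, so false calls from scaling could not show either. Alternatives were DESeq2, limma-voom, RLE scaling, other filters and thresholds, fits of 2 groups only, the replicate block, fry and leaving out each library. Added after the data were seen were scaling by total counts, leaving out the 2 libraries not in the metadata sheet, leaving out mitochondrial genes with their nuclear copies, and thinning all libraries to 2124367 counts. Group differences of single values were tested with exact 2-sided permutation tests, whose smallest p for 3 against 3 libraries is 0.1. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.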

Results

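Gene expression was measured in MCF7 cells, an estrogen receptor-positive breast adenocarcinoma line, left untreated or incubated for 3, 6, 15, 24 or 48 h with phenolaTi at 54 µM. The 18 libraries were 3 repeats of each of the 6 groups, and untreated cells were the control of every time. The title of the series names the endoplasmic reticulum (ER), and the design asks which transcripts differ from untreated cells after each incubation and which differ between consecutive times. Nothing says that the repeats were separate cultures, so p-values measure only the spread between these samples, which may be technical. Total counts were 5444772 to 7366416 in untreated libraries and 2124367 to 3174453 at 48 h (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow), so later times were measured with fewer counts. Coordinates are those of GRCh38 in GENCODE 29.

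Genes of the mitochondrial genome and their nuclear copies took 29.2% ± 5.07 of the counts in untreated cells and 51.9% ± 3.81 at 48 h (SD, n = 3 per group). The means at 3, 6, 15 and 24 h were 31.7%, 32.2%, 37.9% and 40.6%, and exact permutation tests against untreated gave p = 0.6, 0.5, 0.1 and 0.1, and 0.1 at 48 h. By replicate number, the share lay above untreated in 2 of 3 pairs of libraries at 3 and 6 h and in 3 of 3 from 15 h on. The 13 mitochondrially encoded mRNAs alone held 16.9% ± 3.59 in untreated cells and 23.7% ± 3.08 at 48 h (exact permutation p = 0.1). At 15 and 24 h they held 18.0% ± 1.34 and 19.1% ± 1.87 (exact permutation p = 0.8 and 0.5 against untreated). The nuclear copies held 12.3% ± 1.5 in untreated cells and 28.2% ± 1.01 at 48 h. Much of the share of the copies lay in the MTRNR2L genes, copies of a mitochondrial ribosomal RNA gene, with 6.48% ± 0.643 and 19.6% ± 0.558. Uniquely mapped reads were 66.5% of the input on average in untreated libraries and 62.5% at 48 h.

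**Figure D1:**
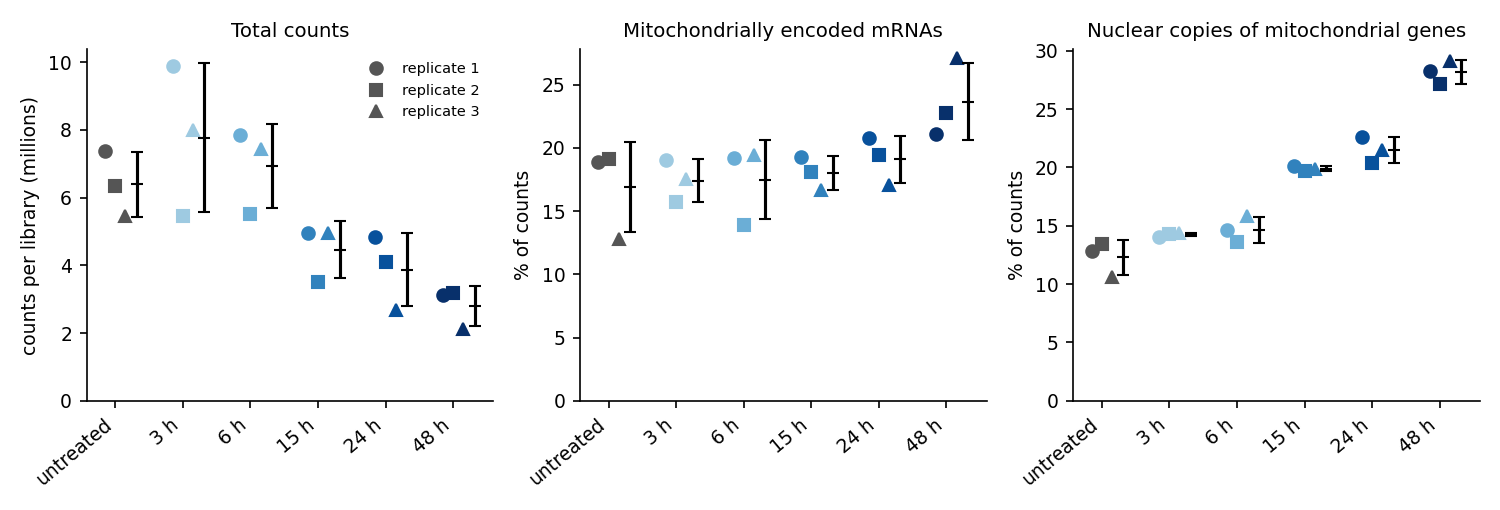
Total counts, percent of counts from the 13 mitochondrially encoded mRNAs and percent from nuclear copies of mitochondrial genes, by incubation time; points are libraries, bars are means ± SD (n = 3). Counts of 48 h libraries lay between 2124367 and 3174453, below all untreated libraries, while the nuclear copies rose in share from a mean of 12.3% to 28.2%.

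The number of changed genes grew with the time of incubation. Of 13211 genes tested, edgeR called 27 at 3 h, 755 at 6 h, 5347 at 15 h, 5928 at 24 h and 6812 at 48 h, and 7988 when all times were tested together. The first principal component held 44.6% of the variance and the second 17.7%. On the second, untreated replicate 3 lay at 0.186, apart from untreated replicates 1 and 2 at -35.4 and -34.9. The groups of treated and untreated libraries did not overlap for 15.6%, 31.2%, 49.97%, 53.6% and 59.9% of the genes at the 5 times, where chance gives 10%. Directions depend on scaling: relative to TMM, scaling by total counts shifted the median log2 change of all genes by -0.12, -0.32, -0.84, -0.92 and -1.03 at 3, 6, 15, 24 and 48 h. Rises given for lists and genes with small changes at 15 h or later are therefore relative to the bulk of the other genes.

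**Figure D2:**
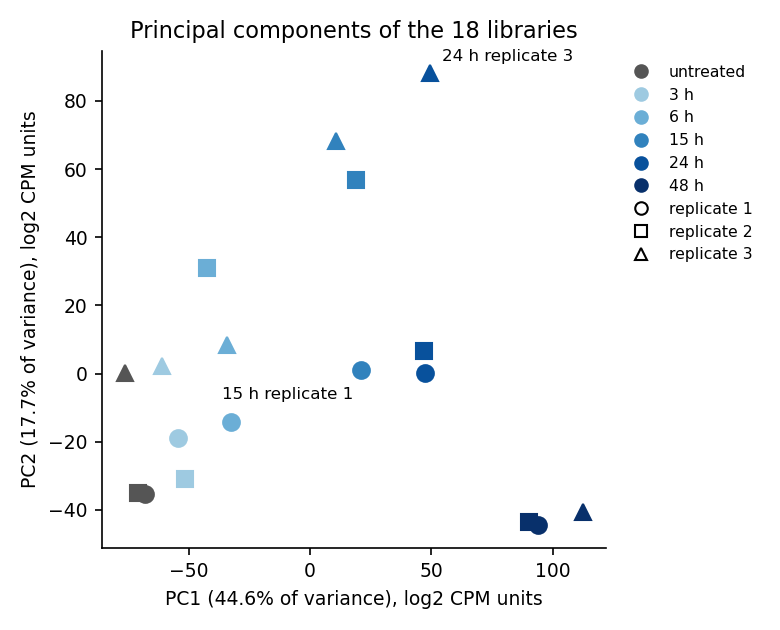
The first 2 principal components of log2 CPM, with 44.6% and 17.7% of the variance; each point is a library, coloured by incubation time and marked by replicate. Libraries of untreated cells and of 48 h lie at opposite ends of the first component.

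**Figure D3:**
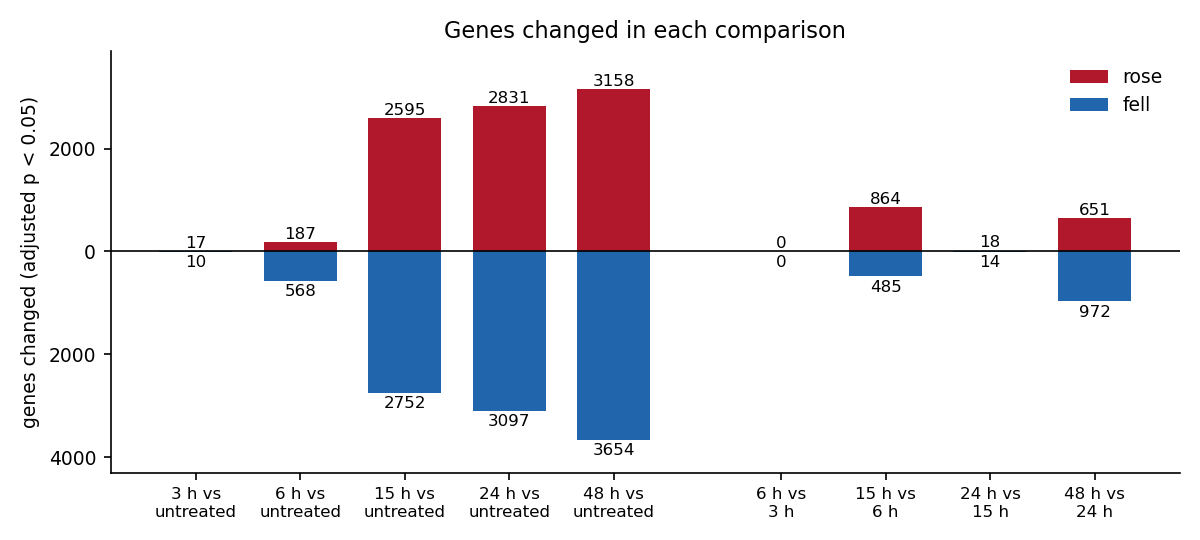
Genes that rose (up) and fell (down) per comparison by edgeR at an adjusted p under 0.05 with TMM scaling. At 48 h 3158 genes rose and 3654 fell, but with total-count scaling 11.5% of the called genes rose in place of 46.4%.

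After 3 h, genes that handle zinc and other metals rose. SLC30A1, a zinc exporter of the plasma membrane (ENSG00000170385, chromosome 1, 211571568 to 211578742), went from 6.33 ± 0.295 to 39.2 ± 4.73 CPM, a log2 change of 2.63 ± 0.25 (adjusted p = 4.56e-06). The metal-binding metallothioneins MT1X (ENSG00000187193, chromosome 16, 56682424 to 56684196) and MT1F rose by 2.37 ± 0.34 and 1.73 ± 0.33 (adjusted p = 0.00196 and 0.0259). In the metallothionein and zinc transport list 3 of 5 measured genes rose, 0 fell and 2 did not pass (5 rose adjusted over the list alone and 4 with the replicate block), with adjusted p = 1.55e-23 by camera and adjusted p = 0.00213 with an estimated correlation. PYGM, the muscle form of glycogen phosphorylase, rose by 2.96 ± 0.43 (adjusted p = 0.00196).

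The NF-kB, heat shock and hypoxia lists passed at 3 h, and 3 h replicate 2 carried much of each shift. Their medians against untreated cells were 3.16, 0.74 and 1.63 in 3 h replicate 2, against 1.02, 0.28 and 0.08 in replicate 1 and 0.24, 0.26 and 0.36 in replicate 3. Without replicate 2 the adjusted p = 0.000534, 4.6e-05 and 0.00228. In the NF-kB list 2 of 11 measured genes rose and 9 did not pass (10 rose adjusted over the list alone and 4 with the replicate block), with a median log2 change of 1.99 and adjusted p = 9.33e-11, but adjusted p = 0.148 with an estimated correlation. The feedback inhibitors TNFAIP3 and NFKBIA rose by 4.95 ± 1.03 and 1.89 ± 0.40 (adjusted p = 0.0437 and 0.0476), TNFAIP3 from 0.156 ± 0.138 to 6.08 ± 8.97 CPM and NFKBIA in 2 of 3 batches. In the heat shock list 1 of 21 genes rose (4 adjusted over the list alone, 2 with the replicate block; adjusted p = 3.52e-09, and adjusted p = 0.0657 with an estimated correlation). HSPA1B rose by 1.68 ± 0.34. HSPA1A, a near-identical gene that makes both uncertain, had 1.34 ± 0.30 (adjusted p = 0.06, and 0.0112 with the replicate block). In the hypoxia and glycolysis list 0 of 24 genes passed (11 rose adjusted over the list alone) with a median of 0.90 (adjusted p = 2.32e-12, and adjusted p = 0.194 with an estimated correlation). BHLHE40 had 1.33 ± 0.34. DDIT3, the transcription factor CHOP of the ER stress response (ENSG00000175197, chromosome 12, 57516588 to 57521737), rose by 1.51 ± 0.31 (adjusted p = 0.0403), while STC2, a secreted glycoprotein, fell by 1.15 (adjusted p = 0.0142). These were the 1 rise and 1 fall among 36 measured PERK-ATF4 genes (4 and 1 adjusted over the list alone, 3 and 1 with the replicate block; adjusted p = 0.00454, and adjusted p = 0.329 with an estimated correlation), whose median of 0.13 became -0.02 with total-count scaling.

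The other genes that rose most at 3 h included MTND6P3, a nuclear copy of a mitochondrial gene and so uncertain. Those that fell most were MIR503HG (-2.81), TMEM177 (-2.10), PNRC2 (-1.82), MOAP1 (-1.62), HDHD3 (-1.57), MED22 (-1.40) and RSRP1 (-1.17). Small shifts of whole lists passed camera as well, and none of these held with an estimated correlation. ER chaperones and degradation were shifted up (0 of 37 genes passed, median 0.28, adjusted p = 2e-05, and adjusted p = 0.0955 with an estimated correlation). DNA replication was shifted down (0 of 37, -0.33, adjusted p = 5.54e-05, then 0.329) and NRF2 targets up (0 of 25, 0.16, adjusted p = 0.00492, then 0.241). Sterol synthesis, ribosomal proteins, mitochondrial mRNAs, the interferon response and fibroblast markers were shifted up, with medians of 0.14, 0.11, 0.18, 0.28 and 0.56 (adjusted p = 0.0113, 0.00454, 0.0154, 0.0093 and 0.00543). They had adjusted p = 0.0955, 0.772, 0.562, 0.441 and 0.0955 with an estimated correlation. In 3 h replicates 1, 2 and 3 the medians were 0.016, 0.00022 and 0.34 for ribosomal proteins and -0.025, 0.65 and 0.17 for the interferon response. Those of sterol synthesis were more even, with 0.17, 0.18 and 0.14. Mitosis was shifted down, with -0.21 (adjusted p = 0.00553, then 0.582), and 0 genes of these lists passed. With the replicate block RFC4 of the replication list fell and LDLR of the sterol list rose. Of the 27 genes called, 17 rose and 10 fell (63.0% rose, and 28% of 25 genes with total-count scaling), and the replicate block called 89. Without 1 library the count was 7 (untreated 1), 4 (untreated 2), 17 (3 h replicate 1) or 5 (3 h replicate 2). SLC30A1, PYGM and MT1X kept their calls in every alternative. Without untreated replicate 1 or 2 or 3 h replicate 2 the calls of TNFAIP3, NFKBIA, HSPA1B, MT1F, DDIT3, TMEM177, MED22, MOAP1, MIR503HG and MTND6P3 ended. Leaving out untreated replicate 3 ended those of TNFAIP3, NFKBIA, HSPA1B, DDIT3, MOAP1 and MIR503HG, and leaving out 3 h replicate 1 those of DDIT3, TMEM177, MED22, MOAP1, MIR503HG, RSRP1, PNRC2 and STC2. Lists that lost their call without 1 library were PERK-ATF4 (untreated 1 or 2), replication and interferon (3 h replicate 2), mitosis and ribosomal proteins (untreated 1 or 2 or 3 h replicate 3), mitochondrial mRNAs (untreated 3 or 3 h replicate 1 or 3) and fibroblast markers (untreated 3).

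After 6 h, the xenobiotic-metabolising enzymes CYP1B1 and CYP1A1 were among the largest rises. CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902) went from 42.5 ± 5.17 to 225 ± 77.5 CPM, a log2 change of 2.40 ± 0.28 (adjusted p = 4.98e-05). CYP1A1 had 1 count over the 3 untreated libraries and 146 at 6 h, a ratio of 171 with a counting interval of 30.2 to 6795 (adjusted p = 9.92e-05). SLC30A1, MT1X and PYGM rose by 2.70 ± 0.25, 2.39 ± 0.34 and 3.07 ± 0.43, and 4 of 5 measured genes of the metallothionein and zinc transport list rose (4 adjusted over the list alone; adjusted p = 4.66e-11, and adjusted p = 0.0223 with an estimated correlation). In the sterol list 2 of 22 genes rose and 20 did not pass (3 rose adjusted over the list alone and 3 with the replicate block; adjusted p = 0.00092, and adjusted p = 0.0419 with an estimated correlation). These were the receptor LDLR, by 1.49 ± 0.28, and the enzyme MSMO1, by 0.61 ± 0.18, though the list's median of 0.29 became -0.06 with total-count scaling.

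The ER chaperone HSPA5, also called BiP (ENSG00000044574, chromosome 9, 125234853 to 125241330), rose at 6 h by 0.81 ± 0.16 (adjusted p = 0.00482), while XBP1, a transcription factor of the unfolded protein response (ENSG00000100219, chromosome 22, 28794555 to 28800597), fell by 1.10 (adjusted p = 0.00197). In their list 1 of 37 genes rose, 2 fell and 34 did not pass (8 and 2 adjusted over the list alone, 7 and 2 with the replicate block; adjusted p = 0.000117, and adjusted p = 0.135 with an estimated correlation). Cell cycle genes fell. They were 4 of 32 mitosis genes (4 adjusted over the list alone; adjusted p = 0.00105, and adjusted p = 0.562 with an estimated correlation), among them NDC80 (-1.76 ± 0.35) and CCNB1 (-1.05 ± 0.23). In replication 2 of 37 genes fell (6 adjusted over the list alone, 6 with the replicate block; adjusted p = 0.00127, and adjusted p = 0.456 with an estimated correlation), the clamp loader subunits RFC4 (-2.19 ± 0.29) and RFC3 (-1.66 ± 0.32). Ribosomal proteins (0 of 78 passed, median 0.53), the nuclear-encoded respiratory chain (0 of 44, 0.41), mitochondrial mRNAs (0 of 13, 0.47), NRF2 targets (1 of 25 rose, 0.38), hypoxia and glycolysis (2 of 24 rose, 0.46, BHLHE40 by 1.97 ± 0.34) and NF-kB genes (0 of 11, 1.29, and 1.24 with a gene at 0 counts set to its bound) were shifted up. With the replicate block 38 ribosomal proteins, 10 respiratory chain genes, 2 mitochondrial mRNAs (MT-CYB and MT-ND6), 4 NRF2 targets, 6 hypoxia genes and 1 NF-kB gene (NFKBIA) rose. The adjusted p of the lists = 3.66e-17, 3.15e-07, 0.000556, 0.00266, 0.00245 and 0.0341 became adjusted p = 0.45, 0.475, 0.42, 0.194, 0.562 and 0.582 with an estimated correlation. Heat shock and autophagy genes were shifted up by 0.31 and 0.34 (adjusted p = 0.00665 and 0.0208; adjusted p = 0.329 and 0.475 with an estimated correlation), which total-count scaling turned to -0.05 and -0.02, and the replicate block called 3 rises in the first and 5 rises and 1 fall in the second.

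In the estrogen list at 6 h 4 of 28 genes fell (5 with the replicate block), including PGR (-1.30 ± 0.34) and AREG (-1.26 ± 0.32), and the list did not pass (adjusted p = 0.128). TBX4 also rose (3.25), and the largest falls were MIR503HG (-3.39), TMEM177 (-3.33), HDHD3 (-2.83), EFNA4 (-2.76), RTL10 (-2.76) and EGLN2 (-2.70). UCKL1-AS1, MTCYBP36, LMNTD2-AS1 and PNRC2P1, also among the largest changes, are antisense genes or copies of other genes and uncertain. Of 755 called genes 187 rose and 568 fell, the replicate block called 1542, of which 638 rose and 904 fell, and total-count scaling called 1692 of which 4.55% rose in place of 24.8%. The count was 361 or 303 without untreated replicate 1 or 2 and 438, 424 or 198 without 6 h replicate 1, 2 or 3. PGR and AREG lost their calls without untreated replicate 1 or 6 h replicate 3, PGR also without untreated replicate 2 or 6 h replicate 2 and AREG without 6 h replicate 1. CCNB1 lost its call without untreated replicate 2 or 6 h replicate 3, MSMO1 in all 6 leave-outs and UCKL1-AS1 without untreated replicate 1 or 6 h replicate 1. EGLN2 lost its call without 6 h replicate 1 and RTL10 without 6 h replicate 3. The NF-kB list lost its call without untreated replicate 3 or 6 h replicate 1, and autophagy without untreated replicate 1 or 2 or 6 h replicate 3.

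After 15 h, cytosolic ribosomal protein genes, mitochondrially encoded mRNAs and nuclear-encoded respiratory chain genes rose as groups, the last with TMM but not with total-count scaling. All 78 measured cytosolic ribosomal protein genes rose, for example RPL35 by 1.56 ± 0.21 and RPS12 by 1.5 ± 0.21 (78 adjusted over the list alone; adjusted p = 1.04e-35, and adjusted p = 0.245 with an estimated correlation). All 13 mitochondrially encoded mRNAs rose, MT-ND4L by 1.64 ± 0.24 (13 adjusted over the list alone, adjusted p = 2.24e-07, and adjusted p = 0.194 with an estimated correlation). The share of mitochondrial counts with nuclear copies was 37.9% ± 1.45. The 13 mRNAs alone held 18.0% ± 1.34, against 16.9% ± 3.59 in untreated cells (exact permutation p = 0.8). Both groups have many near-identical copies in the genome and are uncertain. Of 44 nuclear-encoded respiratory chain genes 32 rose and 12 did not pass (36 adjusted over the list alone; adjusted p = 1.12e-10, and adjusted p = 0.376 with an estimated correlation), among them UQCRQ by 1.60 ± 0.23. The medians of the ribosomal and mitochondrial mRNA lists stayed above 0 with total-count scaling (0.42 and 0.24), and that of the respiratory chain went from 0.83 to -0.10.

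Chaperone and redox genes were higher at 15 h, and cell cycle genes lower. In the ER chaperone and degradation list 16 of 37 genes rose, 2 fell and 19 did not pass (19 and 2 adjusted over the list alone; adjusted p = 0.00665, and adjusted p = 0.262 with an estimated correlation). HSPA5 rose by 0.98 ± 0.16 (0.05 with total-count scaling) and the disulfide isomerases PDIA6 and P4HB by 1.08 ± 0.19 and 1.06 ± 0.19, while XBP1 fell by 2.15. In the NRF2 list 10 of 25 genes rose and 3 fell (12 and 3 adjusted over the list alone; adjusted p = 0.00665, and adjusted p = 0.262 with an estimated correlation), G6PD, TXN and FTH1 by 1.28 ± 0.18, 1.31 ± 0.21 and 1.62 ± 0.26. With total-count scaling the medians of these 2 lists turned from 0.70 and 0.53 to -0.25 and -0.37. In mitosis 17 of 32 genes fell and 0 rose (17 adjusted over the list alone; adjusted p = 5.54e-05, and adjusted p = 0.464 with an estimated correlation), among them CCNB1 (-2.05) and AURKB (-1.47). In replication 10 of 37 fell and 3 rose (8 and 3 adjusted over the list alone; adjusted p = 0.00806, and adjusted p = 0.562 with an estimated correlation), RFC4 most (-3.81). In hypoxia and glycolysis 9 of 24 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.00401, and adjusted p = 0.568 with an estimated correlation), ALDOA by 1.84 ± 0.20, and the median of 0.48 became -0.41 with total-count scaling. Metallothionein and zinc genes stayed up, with 4 of 5 (4 adjusted over the list alone; adjusted p = 2.97e-05, and adjusted p = 0.0955 with an estimated correlation) and SLC30A1 at 3.33 ± 0.26.

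The genes that rose most at 15 h had few counts in untreated cells. PYGM went from 1.22 ± 0.507 to 24.6 ± 6.04 CPM (4.27 ± 0.43), SV2A, a synaptic vesicle protein, rose by 4.07 ± 0.65, CGA, the alpha subunit of glycoprotein hormones, by 3.95 ± 0.54. POU2F2, ATP4B, POU2F1-DT, FGF18 and LRRN4CL rose by 3.66, 3.65, 3.62, 3.38 and 3.37. Of the 4 measured leukocyte markers 2 rose (2 adjusted over the list alone; adjusted p = 0.00716, and adjusted p = 0.0955 with an estimated correlation), CD79A by 3.19 ± 0.33 and CD14 by 3.09 ± 0.55. Of 7 fibroblast and mesenchymal markers 3 rose (3 adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.141 with an estimated correlation), COL6A3 by 2.05 ± 0.22 and VIM by 2.45 ± 0.61. Among the largest falls, EFNA4 had 3 counts against 419 in untreated cells (52.1-fold lower, 17.7 to 254), GSC had 1 (58.2-fold lower, 10.3 to 2314), UBR5-DT 2 (22.2-fold, 6.01 to 185) and ELF5 3 (16.9-fold, 5.67 to 83.1). OSBPL5, ZNF691, A1BG-AS1 and BCL9P1 fell as well (-4.59, -4.46, -4.32 and -4.17). Of 5347 called genes 2595 rose and 2752 fell (48.5% rose), and total-count scaling called 7733 of which 7.84% rose. Autophagy genes (11 of 26 rose, 3 fell; adjusted p = 0.0468, and adjusted p = 0.562 with an estimated correlation) lost their call without any library but untreated replicate 3. The fibroblast list lost its call without untreated replicate 3 or 15 h replicate 1, and both medians (0.50 and 0.72) turned below 0 with total-count scaling.

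After 24 h, p53 target genes rose as a group. In their list 16 of 27 genes rose, 2 fell and 9 did not pass (17 and 2 adjusted over the list alone), with a median log2 change of 1.43 and adjusted p = 1.35e-06, and adjusted p = 0.0419 with an estimated correlation. The cell cycle inhibitor CDKN1A, also called p21 (ENSG00000124762, chromosome 6, 36676460 to 36687339), rose by 2.84 ± 0.33 (adjusted p = 8.96e-07). The stress cytokine GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176) rose by 2.85 ± 0.29 and the growth arrest genes GADD45A and BTG2 by 3.87 ± 0.38 and 3.23 ± 0.34. The antigen receptor component CD79A (ENSG00000105369, chromosome 19, 41877120 to 41881372) went from 1.69 ± 0.239 to 36.8 ± 3.46 CPM (4.42 ± 0.33, adjusted p = 2.93e-09). NR1D1, the clock repressor REV-ERB alpha, went from 6.04 ± 1.32 to 117 ± 30.2 CPM (4.29 ± 0.28, adjusted p = 5.74e-10). CD79A and CD14 were again the 2 of 4 leukocyte markers that rose (2 adjusted over the list alone; adjusted p = 0.00151, and adjusted p = 0.0657 with an estimated correlation).

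The other lists that passed at both 15 and 24 h had the same direction at both times, which the shared untreated libraries favour. In the ER chaperone and degradation list 19 of 37 genes rose and 2 fell (19 and 2 adjusted over the list alone; adjusted p = 0.00236, and adjusted p = 0.194 with an estimated correlation). HSPA5 stood at 1.17 ± 0.16 (0.14 with total-count scaling) and XBP1 at -2.21 ± 0.21, and the list's median of 0.63 became -0.40 with total-count scaling. All 78 ribosomal protein genes and all 13 mitochondrial mRNAs rose (medians 1.44 and 1.26, adjusted p = 7.9e-34 and 9.51e-08, then 0.262 and 0.194 with an estimated correlation). Mitochondrial counts with nuclear copies were 40.6% ± 2.48, and the 13 mRNAs alone 19.1% ± 1.87 (exact permutation p = 0.5 against untreated). In replication 18 of 37 genes fell and 1 rose, and in mitosis 16 of 32 fell and 1 rose (20 and 16 fell adjusted over the list alone; adjusted p = 0.000556 and 0.00127; adjusted p = 0.42 and 0.562 with an estimated correlation). The zinc list had adjusted p = 7.9e-06 (0.0955 with an estimated correlation), with SLC30A1 at 3.75 ± 0.26. Autophagy (14 of 26 rose, 2 fell), NRF2 targets (10 of 25 rose, 2 fell), the respiratory chain (23 of 44 rose, 2 fell), hypoxia and glycolysis (8 of 24 rose, 1 fell) and fibroblast markers (3 of 7 rose) passed camera (adjusted p = 0.0136, 0.0109, 2.63e-06, 0.00266 and 0.0402). They did not pass with an estimated correlation (adjusted p = 0.45, 0.298, 0.529, 0.562 and 0.194), and their medians turned below 0 with total-count scaling. The replicate block gave fibroblast markers adjusted p = 0.0503 and they lost their call without untreated replicate 1 or 3 or 24 h replicate 2 or 3. Autophagy lost its call without untreated replicate 1 or 24 h replicate 3.

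Among the largest rises at 24 h, ALDH8A1 had 127 counts against 3 (139-fold, 46.4 to 681), and PYGM, SV2A, FGF18, CDC20B and POU2F1-DT rose by 5.07, 4.55, 4.46, 3.89 and 3.88. BCL9P1 had 0 counts at 24 h and was at least 21.8-fold lower. LIPT2 and MESP1 had 1 count each (70.2-fold lower, 12.5 to 2786, and 40.6-fold, 7.17 to 1616). ARMCX2 had 2 (27.8-fold, 7.58 to 231), and PCED1B and NEDD1 3 each (25.8-fold, 8.71 to 126, and 27.7-fold, 9.37 to 135). RGS22 and PRR15L fell as well (-4.93 and -4.41). Of 5928 called genes 2831 rose and 3097 fell (47.8% rose), and total-count scaling called 8443 of which 8.95% rose.

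After 48 h, p53 targets rose as a group, and estrogen response and luminal identity genes fell. In the p53 list 22 of 27 genes rose, 1 fell and 4 did not pass (22 and 1 adjusted over the list alone), with a median of 2.25 (adjusted p = 8.84e-14, and adjusted p = 0.00306 with an estimated correlation). GADD45A went from 2.05 ± 1.12 to 128 ± 18.7 CPM (5.99 ± 0.39), CDKN1A from 94.6 ± 36.0 to 1375 ± 484 CPM (3.86, adjusted p = 8.5e-09), and the death receptor TNFRSF10B rose by 3.46 ± 0.26. In the estrogen list 16 of 28 genes fell and 3 rose (17 and 3 adjusted over the list alone; adjusted p = 0.00137, and adjusted p = 0.31 with an estimated correlation), among them the cyclin CCND1 (-1.63) and the growth factor AREG (-4.49). In the luminal list 11 of 18 fell and 4 rose (11 and 5 adjusted over the list alone; adjusted p = 0.00105, and adjusted p = 0.169 with an estimated correlation), among them the transcription factors SPDEF and TFAP2C (-4.45 and -2.55) and CLDN3 (-2.99).

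Interferon, immediate early and nuclear-retained RNA lists passed camera at 48 h. In the interferon list 8 of 15 genes rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.00665, and adjusted p = 0.442 with an estimated correlation), with IFIT1 at 3.82 ± 0.41 and IRF9 at 4.42 ± 0.53. The list's median was 0.79 and 1.07 in replicates 1 and 2 but 0.08 in replicate 3, where 0 of the 15 genes were highest. IFIT2 had 148 counts against 3 (245-fold, 82.2 to 1202). Of 19 immediate early genes 9 rose (9 adjusted over the list alone; adjusted p = 0.00716, and adjusted p = 0.45 with an estimated correlation), IER5 by 3.54 ± 0.35. The medians of both lists, 0.84 and 0.80, turned to -0.43 and -0.30 with total-count scaling. Of the 7 measured genes of the nuclear-retained RNA list 5 rose (6 adjusted over the list alone, adjusted p = 0.00266, and adjusted p = 0.135 with an estimated correlation), among them SNHG1 by 2.00 ± 0.24 and SNHG12 by 1.89 ± 0.22. These 2 are host genes of small nucleolar RNAs, and where their RNA lay in the cell was not measured. In replication 21 of 37 genes fell and 1 rose (21 and 1 adjusted over the list alone; adjusted p = 0.00127, and adjusted p = 0.45 with an estimated correlation), RFC4 most (-4.47). In mitosis 11 of 32 fell and 1 rose (adjusted p = 0.0147, lost without 48 h replicate 3, and adjusted p = 0.607 with an estimated correlation). The median of the mitosis list was -1.73 in 48 h replicate 3, against -0.32 and -0.23 in replicates 1 and 2. Ribosomal proteins (72 of 78 rose, median 1.21) and mitochondrial mRNAs (13 of 13, 1.68) had adjusted p = 1.66e-18 and 7.18e-10 (adjusted p = 0.442 and 0.148 with an estimated correlation), beside 51.9% ± 3.81 mitochondrial counts with nuclear copies. Their medians were 0.09 and 0.53 with total-count scaling. In the zinc list 4 of 5 genes rose (4 adjusted over the list alone; adjusted p = 0.00285, and adjusted p = 0.194 with an estimated correlation), SLC30A1 by 4.68 ± 0.27. Of 4 leukocyte markers 2 rose, CD79A by 5.89 ± 0.34 and CD14 by 5.96 ± 0.49, and CORO1A fell by 0.81, though not without untreated replicate 1 or 48 h replicate 1 or 3 (list adjusted p = 0.00401, and adjusted p = 0.0955 with an estimated correlation).

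NF-kB genes at 48 h did not pass as a list (5 of 11 rose, median 2.04, adjusted p = 0.094), although NFKBIA rose by 3.42 ± 0.42 and CXCL8, with 16 counts against 0, was at least 26.5-fold higher. In hypoxia and glycolysis 10 of 24 genes rose and 5 fell, BHLHE40 by 4.61 ± 0.35 (adjusted p = 0.0367, lost in all 6 leave-outs; adjusted p = 0.662 with an estimated correlation), and its median of 0.62 became -0.48 with total-count scaling. Fibroblast markers (3 of 7 rose, COL6A3 by 2.90 ± 0.23; adjusted p = 0.0314, and adjusted p = 0.169 with an estimated correlation) lost their call without any library but 48 h replicate 3. Autophagy genes (11 of 26 rose, 4 fell) had adjusted p = 0.0774, and 0.0322 with the replicate block. The ER list no longer passed (12 of 37 rose, 8 fell, adjusted p = 0.472). Neither did the PERK-ATF4 (9 of 36 rose, 15 fell, adjusted p = 0.964) and heat shock lists (5 of 21 rose, 7 fell, adjusted p = 0.546). The PERK-ATF4 median of -0.48 and the upward sign of camera differed. Iron handling (2 of 12 rose, 4 fell), ribosome biogenesis (10 of 34 rose, 7 fell) and the BCL2 family with death receptors (6 of 21 rose, 9 fell) had adjusted p = 0.976, 0.469 and 0.786 at 48 h and passed at no time with all libraries. Ribosome biogenesis was nearest at 15 h, where 13 of 34 genes fell and 3 rose (median -0.51, and -1.43 with total-count scaling; adjusted p = 0.0554). It passed there without untreated replicate 2 or 3 or 15 h replicate 1 or 2 (adjusted p = 0.0476, 0.0146, 0.0498 and 0.0357), and at 3 h without untreated replicate 3 (0.0229).

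The largest rises at 48 h were again genes with few counts in untreated cells. GAL3ST1 had 122 counts against 1 (606-fold, 107 to 24129), SLC22A14 180 against 2 (447-fold, 122 to 3720), DKFZP434A062 139 against 3 (230-fold, 77.1 to 1130) and ALDH8A1 133 against 3 (220-fold, 73.7 to 1081). IGF2BP3 and IGF2BP2, which bind mRNA, rose by 6.50 ± 0.66 and 6.33 ± 0.71, and KRT18P61, a pseudogene and uncertain, by 6.38 ± 0.67. ARHGAP8, LYPLAL1, STRADB, GYG2, FRAT1 and TM9SF5P had 0 counts at 48 h and were at least 11.3-, 8.66-, 8.86-, 8.19-, 8.12- and 8.12-fold lower, and EFNA4 and MOCS1 had 1 count each (84.4-fold lower, 15.1 to 3340, and 62.8-fold, 11.2 to 2489). Of 6812 called genes 3158 rose and 3654 fell (46.4% rose), and total-count scaling called 9012 of which 11.5% rose, with 4687 genes called in the same direction by both.

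**Figure D4:**
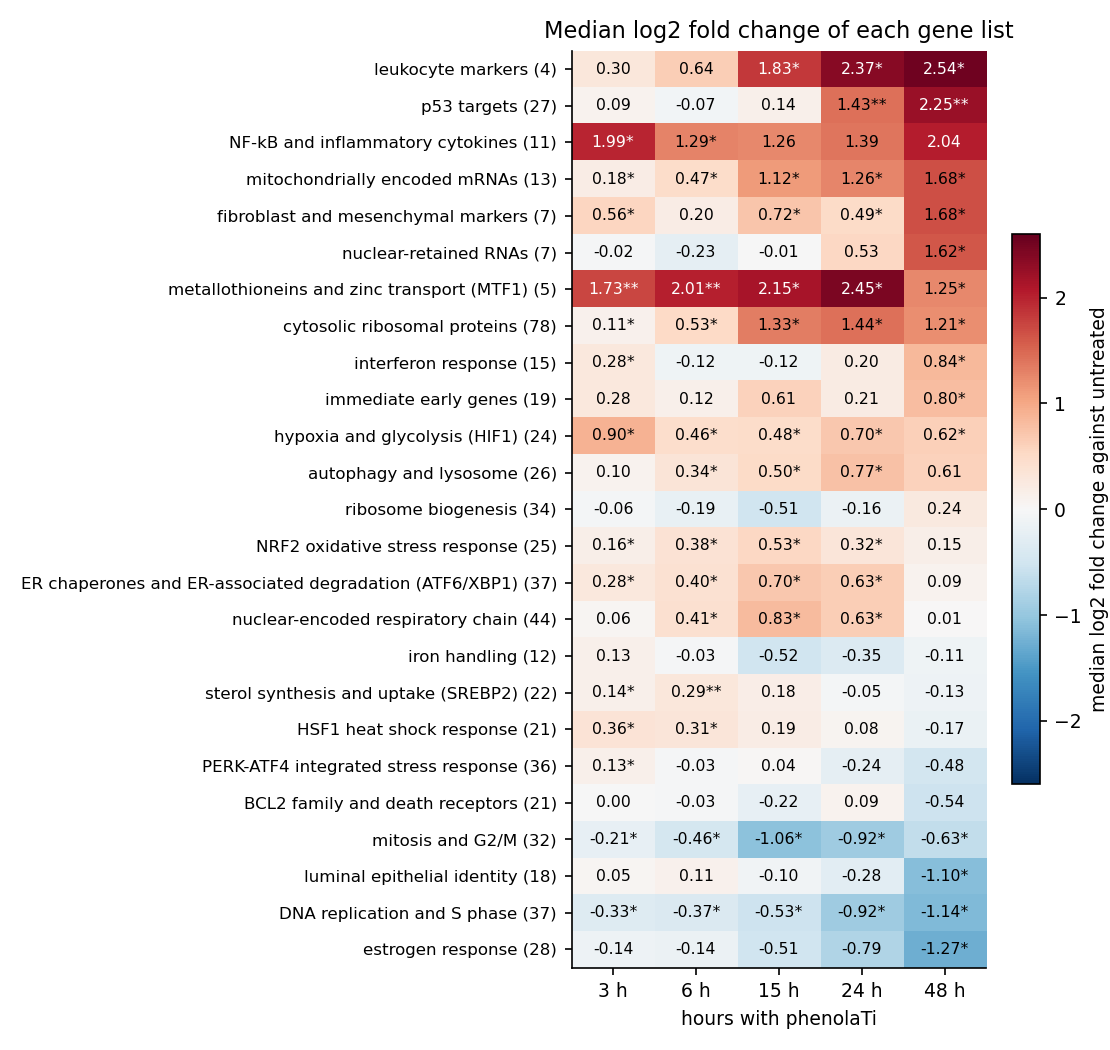
Median log2 change (TMM) of the 25 gene lists at each time, with the number of measured genes in brackets; 1 star marks adjusted p under 0.05 by camera and 2 stars also with an estimated correlation. With total-count scaling the medians of the ER, NRF2, hypoxia, respiratory chain and autophagy lists turn below 0 at 15 and 24 h, while the zinc, p53, ribosomal protein and mitochondrial mRNA lists stay above 0 where they are starred. Some of these are close to 0: ribosomal proteins with 0.002 at 3 h and 0.09 at 48 h, mitochondrial mRNAs with 0.05 at 3 h and the zinc list with 0.14 at 48 h.

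Genes chosen beforehand for ER stress, integrated stress, cell cycle and estrogen response moved apart. HSPA5 rose to 2.01 ± 0.17 at 48 h (344 ± 42.5 against 85.7 ± 7.41 CPM, adjusted p = 3.89e-09) and XBP1 fell by 2.65 (46.9 ± 7.63 against 295 ± 58.6 CPM, adjusted p = 2.76e-09). With total-count scaling the log2 difference of HSPA5 was 0.05, 0.14 and 0.86 at 15, 24 and 48 h. HSP90B1 rose at 15, 24 and 48 h (0.79, 0.98 and 0.86; adjusted p = 0.0034, 0.000448 and 0.00132), and each direction turned with total-count scaling. DDIT3 rose at every time, to 2.93 at 48 h (adjusted p = 2.42e-07). ATF4 rose at 24 and 48 h (0.74 and 1.61, with adjusted p = 0.00788 and 3.6e-06), at 24 h turning with total-count scaling and not called without untreated replicate 1. ATF3 rose from 15 h on (2.37, 2.38 and 3.99) and GDF15 from 6 h on, to 3.25. CHAC1, an ATF4 target, fell at 15 and 24 h (-1.84 and -2.28; adjusted p = 0.0485 and 0.0259), and had -1.23 at 48 h; its call ended at both times without untreated replicate 3 or any treated library, and at 15 h without untreated replicate 1. ASNS fell at 48 h (-1.16, adjusted p = 0.0108; not without 48 h replicate 2). HMOX1 fell at 15 h (-2.47, adjusted p = 0.0139; not without untreated replicate 3 or 15 h replicate 3) and rose at 48 h (2.65, adjusted p = 0.000283). MT2A rose from 6 h on (1.45, 1.85, 2.41 and 1.5) with adjusted p = 0.14 at 3 h and 0.00518 there with the replicate block. CCNB1 fell from 6 h on, to -1.72 at 48 h, and MCM2 fell at 48 h (-0.92, adjusted p = 0.013; not without 48 h replicate 3). At 6 h the calls of DDIT3, GDF15 and MT2A ended without untreated replicate 1 or 2 or 6 h replicate 3, DDIT3 also without 6 h replicate 1 and GDF15 without 6 h replicate 2. The estrogen-induced genes TFF1 (ENSG00000160182, chromosome 21, 42362282 to 42366594) and GREB1 (ENSG00000196208, chromosome 2, 11482341 to 11642788) went opposite ways from 15 h on. TFF1 rose (1.38, 1.30 and 0.86, the last turning with total-count scaling and not called without untreated replicate 1) and GREB1 fell (-1.13, -1.53 and -1.70). DNAJB9, HERPUD1, SDF2L1, TRIB3, MKI67 and HSPA1A passed at no time, with HERPUD1, DNAJB9, MKI67, TRIB3 and SDF2L1 at 0.98, 0.56, 0.01, -0.32 and -0.64 at 48 h (adjusted p = 0.052, 0.396, 0.994, 0.418 and 0.0612). MKI67 had 6.36, 6.27 and 4.71 log2 CPM in untreated replicates 1, 2 and 3, so its change averages over 1 low control library.

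**Figure D5:**
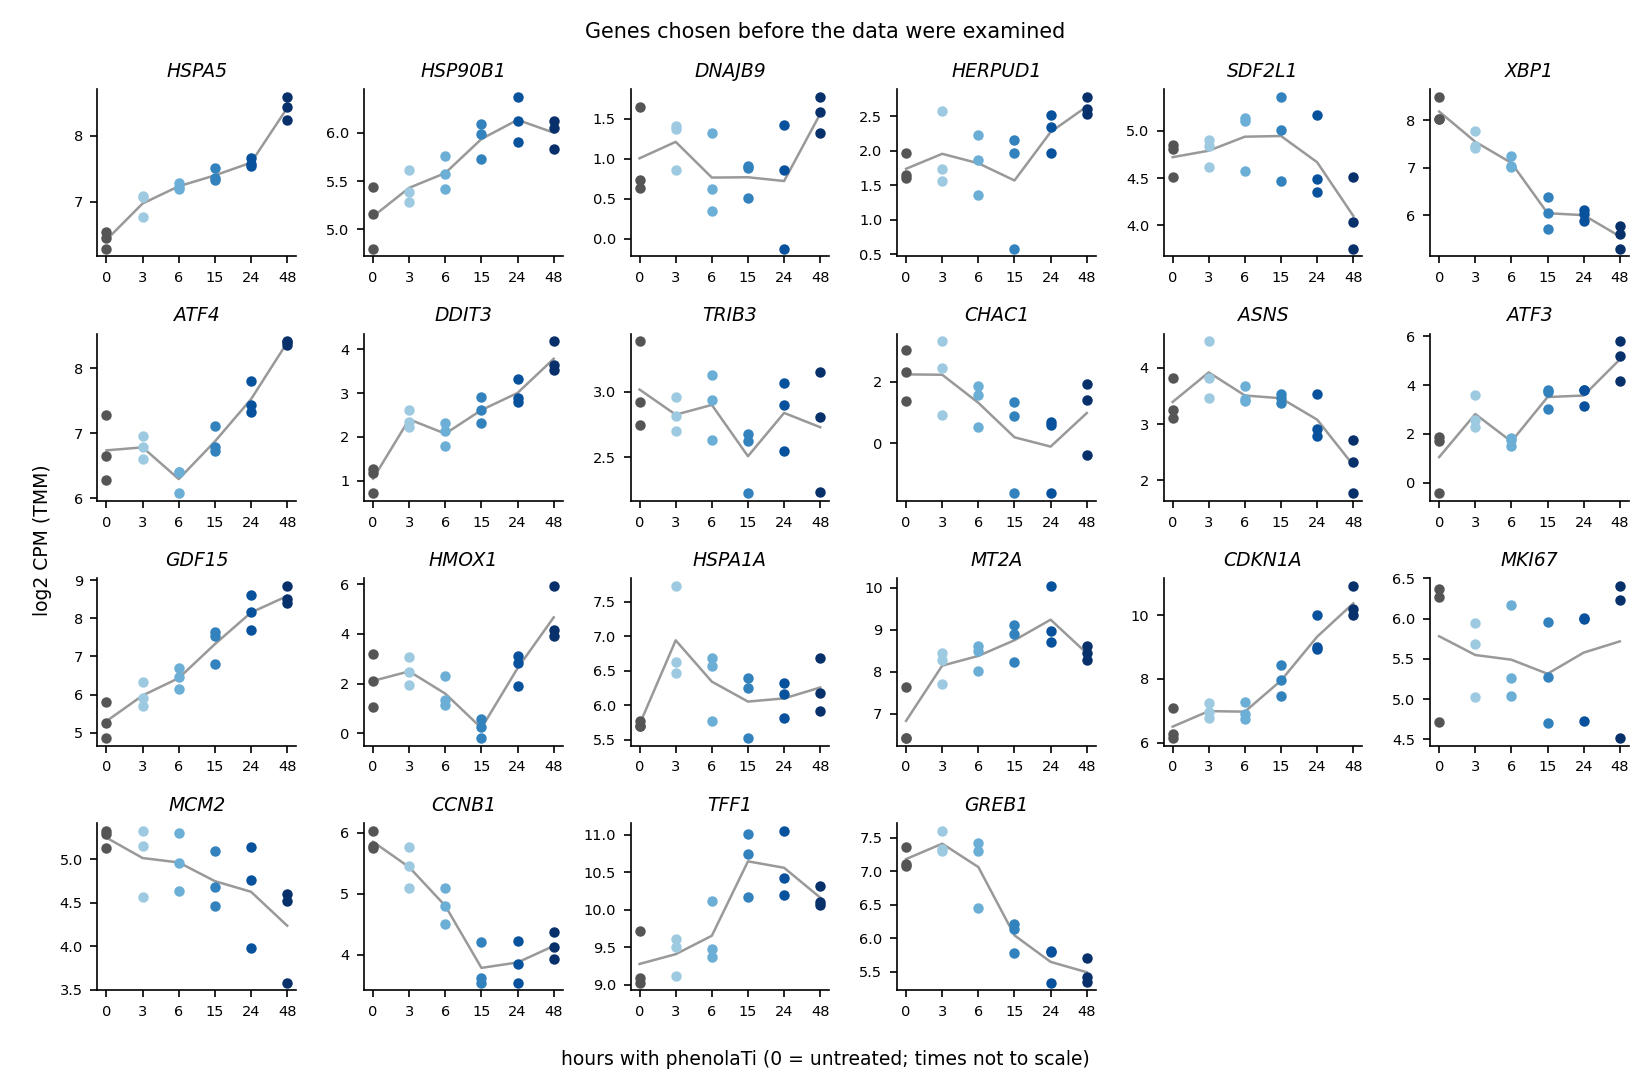
Log2 CPM of the 22 genes chosen beforehand, by incubation time (not to scale); points are libraries and lines join group means. HSPA5 goes from a mean of 85.7 CPM untreated to 344 at 48 h and XBP1 from 295 to 46.9, while HSP90B1 changes direction with total-count scaling from 15 h on. The log2 difference of HSPA5 is 0.05, 0.14 and 0.86 with total-count scaling at 15, 24 and 48 h.

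Between 3 and 6 h edgeR called 0 genes, with 1121 at an unadjusted p under 0.05, 43 by DESeq2, 2 by limma-voom and 4 with the replicate block. Between 6 and 15 h CD79A rose by 2.74 ± 0.33 (adjusted p = 4.56e-05) and POU2F1-DT by 2.60, while the complement receptor C5AR1, the sulfate transporter SLC26A2 and RGS22 fell (-2.27, -2.26 and -2.22). MTND3P25, MTRNR2L9 and DHRS4-AS1 were also among the largest changes (2.36, 2.33 and -2.31) and are uncertain as copies or antisense genes. ATF3, CDKN1A, TFF1 and GDF15 rose over this interval (1.97, 1.01, 0.99 and 0.92), and GREB1, XBP1 and CCNB1 fell (-1.07, -1.05 and -0.998). In all 1349 genes differed, 864 up and 485 down (64.0% up, and 4.07% of 3387 with total-count scaling). The count was 268 or 358 without 6 h replicate 1 or 3 and 273 or 340 without 15 h replicate 2 or 3, and without any of these 4 the calls of CDKN1A, TFF1 and GDF15 ended. CDKN1A and CCNB1 also lost theirs without 6 h replicate 2, and CCNB1 without 6 h replicate 1 or 15 h replicate 2 or 3. ATF3 lost its call without 6 h replicate 1 or 3 or 15 h replicate 3, and RGS22 without 6 h replicate 3 or 15 h replicate 2 or 3.

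Between 15 and 24 h the clearest rise was that of NR1D1, from 27.1 ± 10.8 to 117 ± 30.2 CPM (2.096 ± 0.25, adjusted p = 0.000324). BTG2 rose by 1.85, CSNK1G1 by 1.69 and MRPL20-DT by 1.46, while PIN4, IMMP1L, SPTSSB and the calpain inhibitor CAST fell (-1.47, -1.47, -1.35 and -1.34). CDKN1A and HMOX1 had 1.40 and 2.79 (adjusted p = 0.0549 and 0.134, and 0.000668 and 0.0318 with the replicate block). In all 32 genes differed, 18 up and 14 down (56.25% up, 75.9% with RLE scaling, and 20.2% of 84 with total-count scaling), 103 with the replicate block and 0 when only these 2 groups were fitted. The count was 10 or 1 without 15 h replicate 2 or 3, and 2, 1 or 17 without 24 h replicate 1, 2 or 3; among the named genes NR1D1 alone kept its call in all 6 leave-outs.

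Between 24 and 48 h CHST12, a sulfotransferase, rose from 10.6 ± 11.5 to 85.6 ± 9.03 CPM (2.86 ± 0.50), as did PYCARD-AS1 (3.21, antisense and uncertain), DKFZP434A062 (2.86) and the homeobox gene EN2 (2.86). GNG13, the ER retention receptor KDELR3 and ZMAT5 fell (-2.49, -2.28 and -2.01). MT1X fell from 61.3 ± 23.9 to 13.9 ± 3.40 CPM (-2.097). HMOX1, ATF3, CDKN1A, ATF4 and HSPA5 rose (2.32, 1.61, 1.02, 0.86 and 0.84; adjusted p = 0.0104, 0.0258, 0.0323, 0.0117 and 0.00237). In all 1623 genes differed, 651 up and 972 down (40.1% up, and 19.9% of 1910 with total-count scaling). The count was 914 without 24 h replicate 3 and 1051 without 48 h replicate 1. ATF3 and CDKN1A lost their calls without 24 h replicate 1 or 2 or 48 h replicate 2 or 3, ATF3 also without 24 h replicate 3. HMOX1 lost its call without 24 h replicate 1 or 48 h replicate 3, and ATF4 without 24 h replicate 2.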

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

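Of the tests in this part, those of exchanged labels by p53 targets and principal components, of depth, of nuclear copies and of B cells were chosen after the result was seen. The decision to read the tests of replicate batches and depth as void, and that of a longer 3′ end as undecided, was also settled after their values were seen.

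Effects against untreated cells that differed between consecutive times are given here, each by a test of the difference itself. Between 6 and 15 h 1349 genes differed. The genes chosen by size were CD79A, POU2F1-DT, MTND3P25 and MTRNR2L9 (2.74, 2.599, 2.36 and 2.33) and DHRS4-AS1, C5AR1, SLC26A2 and RGS22 (-2.31, -2.27, -2.26 and -2.22). Among the genes chosen beforehand ATF3, CDKN1A, TFF1 and GDF15 rose (1.97, 1.01, 0.99 and 0.92) and GREB1, XBP1 and CCNB1 fell (-1.07, -1.05 and -0.998). Between 15 and 24 h 32 genes differed, with NR1D1, BTG2, CSNK1G1 and MRPL20-DT up (2.096, 1.85, 1.69 and 1.46) and PIN4, IMMP1L, SPTSSB and CAST down (-1.47, -1.47, -1.35 and -1.34). Between 24 and 48 h 1623 genes differed, with PYCARD-AS1, DKFZP434A062, EN2 and CHST12 up (3.21, 2.86, 2.86 and 2.86) and GNG13, KDELR3, MT1X and ZMAT5 down (-2.49, -2.28, -2.097 and -2.01). Of the genes chosen beforehand HMOX1, ATF3, CDKN1A, ATF4 and HSPA5 rose (2.32, 1.61, 1.02, 0.86 and 0.84). Each of these 36 changes had the same direction in 3 of 3 pairs of equal replicate number. The naming rule required this of the genes chosen by size, so only those chosen beforehand could have differed. For 15 h replicate 1 and 24 h replicate 3 no batch letter is given.

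Each comparison of 3 with 3 libraries has 10 splits, so the share of splits with as many genes cannot fall below 0.1, too few for a share under 0.05. The real split of the comparisons with untreated gave 27, 755, 5347, 5928 and 6812 genes, 1 split of 10 in each case, and the highest of the other splits 0, 0, 1, 0 and 0. Between consecutive times the real split gave 0 (all 10 splits gave as many), 1349, 32 and 1623 genes, and the highest of the others 0, 0, 556 and 0. For a change at any time, the 7988 genes were reached by 1 of 100 regroupings, the real one, with 0 as the highest other. Random groups mix untreated and treated libraries, so this shows only that libraries of 1 group resembled each other. Repeats of 1 culture would do so as well, so chance differences between cultures stay open.

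The split that gave 556 genes in place of 32 set 15 h replicate 1 and 24 h replicates 1 and 2 against 15 h replicates 2 and 3 and 24 h replicate 3, which points to a structure of the samples. It runs in part with the replicate batches, since it parts only replicate 2: deviations from the group means correlated across genes at 0.326, -0.029 and 0.311 between the 15 and 24 h libraries of replicates 1, 2 and 3, the replicate block called 103 genes, and the highest other split that parts all 3 replicate numbers gave 0. Without 15 h replicate 1 and 24 h replicate 3, which the deposited sample sheet does not list, 427 genes differed. On an axis of 5723 genes from 6 h (0) to 48 h (1) these 2 lay at 0.361 and 0.383, between the means of the other 15 h (0.221) and 24 h (0.518) libraries, but exchanged labels are argued against by the median of the p53 targets, where both lay nearer to their own time by a mean margin of -0.93 (spread 0.36), and by the first principal component (-26.2, spread 8.32), although the second went the other way (59.1, spread 11.4). Replicate batches, depth and a slower and a faster response of part of the genes cannot be told apart: with replicate batches taken off, or after thinning to equal depth, the margin on the axis went from -0.0214 (spread 0.0621) to -0.0632 (0.0460) or -0.0479 (0.0672), but both libraries were nearer to their own time to begin with, so these tests say nothing about batches or depth.

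The rise in the share of mitochondrial counts from untreated cells to 48 h is a second pattern. Lower depth alone as the source is argued against within groups, where the library with the lowest total count had the highest share in 1 of 6 groups. Counting the same reads again in nuclear copies is argued against as the whole source at 48 h, where all 3 libraries lay above every untreated library in the mitochondrially encoded mRNAs alone, but stays open at 15 and 24 h. Among the copies, the MTRNR2L genes went from a mean of 6.48% in untreated cells to 13.5%, 14.7% and 19.6% at 15, 24 and 48 h. Their source, a mitochondrial ribosomal RNA gene, is not among the counted genes. Their reads were thus not counted again for a mitochondrial gene, though perhaps for several copies. A loss of nuclear-encoded RNA from treated cells could give the same shares: the median log2 difference of all genes at 48 h was -1.29 with total-count scaling, but without a spike-in or an RNA amount per cell it cannot be told apart from a rise of mitochondrial RNA. The biological difference the design names, the time with phenolaTi, stays open and goes with depth across groups.

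The rise at 48 h of genes with few counts in untreated cells is the third pattern, though the expression filter favoured it. Genes with almost no counts in untreated cells were tested only if another group was high, and they had little room to fall. Shares that rose are therefore read only against each other. RNA from B cells is argued against for CD79A, since CD74, abundant in such cells, had 3.02 ± 1.30 CPM, 2.96% of the 102 ± 27.7 CPM of CD79A. Of 6 leukocyte transcripts 1 rose (CD19, 7.63 against 0.0427 CPM) and the others had too few counts to be tested, which leaves other leukocytes open. Transcription running on from an expressed gene upstream is a candidate explanation for part of the genes, such as CD79A, which starts 4194 bp from the end of RPS19. Of 155 genes with an expressed gene ending within 10 kb upstream on the same strand, 61.3% rose. Where an expressed gene on the opposite strand ended within 10 kb of the start, on either side, 38.6% of 114 rose (ratio 1.59, Fisher's exact p = 0.000326). The windows thus differed between the strands. By distance to the upstream gene, however, the share that rose hardly fell up to 50 kb (58.0% within 5 kb, 64.9% to 10 kb, 55.3% to 20 kb, 54.8% to 50 kb and 36.1% beyond), and genes far from a neighbour, such as ALDH8A1, SLC22A14 and IFIT2, rose as well, so induction of each gene by itself stays open. An unannotated longer 3′ end of the upstream gene would make both move alike. The median difference, gene minus upstream gene, was 2.12, past the bound set beforehand for arguing against it. Random upstream genes gave 1.98 to 2.92, however, and the expression filter favoured such a difference. Spearman's rho between the changes of gene and upstream gene was 0.257, so the test cannot decide how much such ends give.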

How the results depend on the processing

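The tests chosen after the data were seen are 4: scaling by total counts, leaving out the 2 libraries missing from the deposited sample sheet, leaving out mitochondrial genes and their copies, and thinning every library to the total of the smallest. Counts of changed genes stayed within 1.5 times of those reported except as follows, and the cause was not tested, apart from stricter thresholds and fewer counts or libraries. DESeq2 gave 112 genes at 3 h, 43 between 3 and 6 h and 291 between 15 and 24 h, limma-voom 109 at 3 h, 1360 at 6 h, 2 between 3 and 6 h and 21 between 15 and 24 h, and no filter on low counts 191, 63 and 108 at 3 h, between 3 and 6 h and between 15 and 24 h. Between 15 and 24 h a mean of at least 20 counts gave 63 and a fit of the 2 groups only 0. The replicate block gave 89 at 3 h, 1542 at 6 h, 4 between 3 and 6 h and 103 between 15 and 24 h. Total-count scaling gave 1692 at 6 h, 1 between 3 and 6 h, 3387 between 6 and 15 h and 84 between 15 and 24 h. Without the 2 unlisted libraries 78 genes were called at 3 h, 1340 at 6 h, 2089 between 6 and 15 h and 427 between 15 and 24 h. Thinning gave 7, 162, 2885, 3463 and 4152 genes at 3, 6, 15, 24 and 48 h, 521, 9 and 793 between 6 and 15, 15 and 24, and 24 and 48 h, and 4811 at any time, so depth limits the counts. An adjusted p under 0.01 left 4, 226 and 3490 genes at 3, 6 and 15 h and 174, 1 and 629 between 6 and 15, 15 and 24, and 24 and 48 h, and a 2-fold change as well left 652 between 6 and 15 h. Leaving out 1 library gave 4 to 38 genes at 3 h, 198 to 781 at 6 h, 4292 to 5181 at 15 h, 5016 to 5723 at 24 h, 6014 to 6588 at 48 h, 0 to 2 between 3 and 6 h, 268 to 1693 between 6 and 15 h, 1 to 44 between 15 and 24 h, 914 to 1502 between 24 and 48 h and 7506 to 8712 at any time. Between 3 and 6 h 3 h replicate 3 gave 2 and 6 h replicate 2 gave 1. Of 14, 13, 12, 13 and 14 lists past the threshold at 3, 6, 15, 24 and 48 h, an estimated correlation left 1, 2, 0, 1 and 1, fry called 5 at 3 h, and leave-outs gave 11 to 16, 12 to 14, 11 to 13, 12 to 14 and 12 to 13. With total-count scaling HSP90B1 (15, 24 and 48 h), ATF4 (24 h) and TFF1 (48 h) turned among the called genes chosen beforehand, as did the medians of called lists: PERK-ATF4 at 3 h, heat shock, sterol and autophagy at 6 h, ER, NRF2, respiratory chain, hypoxia, autophagy and fibroblast markers at 15 and 24 h, and hypoxia, interferon and immediate early genes at 48 h. HSPA5 did not turn with total-count scaling, but its log2 difference shrank from 0.98, 1.17 and 2.00 to 0.05, 0.14 and 0.86 at 15, 24 and 48 h. In the other alternatives no called gene or list reversed its direction. Of 748 gene results 454 were called, and of these 64 lost their call on thinning, 22 in a fit of the 2 groups only, 16 with limma-voom, 12 without a filter, 8 without the 2 unlisted libraries, 6 with RLE, 6 without mitochondrial genes, 5 with DESeq2 and 4 with a mean of at least 20 counts. Over the leave-outs of 1 library, lists lost their call 44 times and came to pass 21 times. Signs changed for 170 uncalled gene results and 44 uncalled list results. Of all genes in the lists, the replicate block added 9, 89, 28, 22 and 23 calls at 3, 6, 15, 24 and 48 h, counting a gene once per list, and ended 1. In the NF-kB and interferon lists at 15 h it called 5 and 4 rises in place of 3 and 2. Apart from these, the replicate block changed no other call than those given with the results, 46 genes that came to pass, TAGLN at 24 h, which no longer did, and 3 lists: autophagy at 3 and 48 h (adjusted p = 0.0417 and 0.0322) and fibroblast markers at 24 h (0.0503).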

Other observations

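All tests of gene families and of the aryl hydrocarbon receptor in this part were chosen after the main results were seen, the predictions for the receptor and for gene span having been written before their own values were. That the receptor test decides nothing was settled after its value was seen.

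Mitochondrial ribosomal protein genes, which the nucleus encodes, went the opposite way from the cytosolic ones at 48 h with TMM scaling. With total-count scaling the median of the cytosolic ones was 0.09. Of 73 measured, 49 fell and 3 rose, with a median log2 change of -1.20 (adjusted p = 1.99e-07 over 9 families and 5 times by camera, and adjusted p = 0.301 with an estimated correlation), and of -2.32 with total-count scaling. At 24 h 25 fell and 7 rose (median -0.59, adjusted p = 0.0127, and adjusted p = 0.583 with an estimated correlation). Cytosolic and mitochondrial aminoacyl-tRNA synthetases also fell at 48 h, 16 of 33 with 1 rise (-0.84, adjusted p = 0.0127, and adjusted p = 0.207 with an estimated correlation). Zinc finger genes of the ZNF family were lower early: of 309, 0 passed at 3 h (-0.27, adjusted p = 4.24e-05), 18 fell and 2 rose at 6 h (-0.42, adjusted p = 0.000231) and 84 fell and 28 rose at 15 h (-0.60, adjusted p = 0.0193), with adjusted p = 0.249, 0.257 and 0.39 with an estimated correlation.

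Histone genes rose at 15 h, 13 of 40 with 1 fall (median 0.73, adjusted p = 0.00199, and adjusted p = 0.257 with an estimated correlation), and SRSF splicing factors at 48 h, 7 of 11 with 1 fall (0.77, adjusted p = 0.0409, and adjusted p = 0.301 with an estimated correlation), but total-count scaling turned the medians to -0.09 and -0.36. Proteasome subunits at 6 h (0 of 34 passed, 0.28, adjusted p = 0.0193, and adjusted p = 0.52 with an estimated correlation) turned to -0.06 in the same way, and mediator subunits were lower at 6 h (3 of 29 fell, -0.27, adjusted p = 0.0267, and adjusted p = 0.207 with an estimated correlation). Solute carriers and eukaryotic initiation factors passed at no time.

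CYP1A1 and CYP1B1 are targets of the aryl hydrocarbon receptor, and its activation is a candidate explanation for their rise at 6 h. Of 7 other targets 1 rose at 6 h, TIPARP (1.62 ± 0.40, adjusted p = 0.0195). That met the bound set for arguing against the receptor, but only 3 of the 7 had enough counts to be tested, and AHRR had 1.78 ± 0.56 (adjusted p = 0.0612) and NQO1 0.50 ± 0.18 (adjusted p = 0.0961), so the test leaves the question open. At 15 h these 3 rose (TIPARP 2.85, AHRR 2.26 and NQO1 0.87).

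A block of transcription elongation could lower long genes more than short ones. Across 10717 genes, which are not independent replicates, Spearman's rho of the 48 h change with gene span was -0.0269, and -0.068 with GC content, transcript length, expression and exon number regressed out, the weakest of the 3 batches having -0.0559. With GC content, transcript length or expression alone regressed out, rho was -0.0177, -0.106 or -0.00328. With a rho so near 0 at 48 h, the share of it that each property leaves decides nothing there, so such a block cannot be told apart from these properties. At 3, 6, 15 and 24 h rho was 0.103, -0.0159, -0.144 and -0.128, and with all 4 properties regressed out it was 0.0866, 0.0929, 0.0187 and -0.0114. At 48 h 26.8% of the fifth of genes with the longest span fell and 14.8% rose, against 31.9% and 26.4% of the fifth with the shortest.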
